A study of Homo sapiens with 24 samples.

How the data were processed

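RNA from 24 cultures, 4 of each of 6 lines (Ramos and the 5 doxorubicin-resistant lines), had been hybridised to Illumina bead arrays, 1 sample per array. Per the labels' protocols and the design text, the 4 cultures of a line were split from 1 culture, cells grew in RPMI with fetal bovine serum, resistant lines in the presence of their drug concentration, and RNA was purified on columns and converted to biotin-labelled copies with a commercial kit. The intensity values were deposited by the authors as mean bead signals per probe, and per the file headers and the values they are neither background-subtracted nor normalized between arrays. The p-values deposited beside them are detection p-values per probe and array, per the file headers, and their steps fit a rank among negative control beads. The log2 values in the authors' deposited table matched log2 of quantile-normalized signals with no background subtraction, with a highest absolute difference of 0.0059 and a median one of 0.00018, and 24 of 24 columns correlated best with their own array (lowest r 0.9998). The tool lumi is named per the submitters' processing notes, with no version or role, and the scanner software, the genome build and the annotation are not given in the sources used here. Groups and replicate numbers came from the sample labels. No 2 arrays held identical values, and r within a line ran from 0.990 to 0.994.

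The analysis started from the unnormalized intensities. Background was corrected with normexp using negative control parameters inferred from the detection p-values (limma nec, offset 16), and arrays were quantile-normalized and taken to log2. A probe was kept where its detection p was under 0.01 on at least 3 of the 4 arrays of at least 1 line, which left 15765 of 47323 probes (33.3%). Of all probes 30113 carried 1 gene symbol, 8 several and 17202 none in the annotation used here. Symbols were updated through Entrez identifiers for 30074 probes and kept as annotated for 39, and 3260 kept probes without a single symbol entered the fit and were not named. A gene was read from its brightest kept probe, 2450 genes having more than 1, and the text says where the other probes of a named gene differ in sign. This gave 9533 genes.

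Tests used limma 3.58.1 in R 4.3.3. A model with a mean per line over all 24 arrays (18 residual and 3.99 prior degrees of freedom) gave the 9 comparisons, each resistant line against Ramos and each line against the one before it, with moderated statistics and Benjamini-Hochberg adjustment over the 15765 probes. A gene passed at an adjusted p under 0.05, and the counts also required a fitted 2-fold change, also where a probe was undetected in a line. A gene undetected by all its probes on every array of a line has only a bound there. Its "at least N-fold" value sets the mean of the brighter line against the mean, over the arrays of the dimmer one, of the higher of the lowest detected signal and the probe's own. Where only the probe read was undetected and another was detected, no fold is given. A median "at bounds" sets such genes of a list at these values. In all, 28 gene lists were fixed beforehand and 27 with at least 4 measured genes were tested with camera in limma, at a preset correlation of 0.01 and with an estimated one, adjusted over the 27. Named genes followed a rule fixed beforehand. It took the 10 highest and 10 lowest fold changes for Dox1000 versus Ramos and 5 and 5 elsewhere, among genes that passed and whose 4 arrays all lay beyond the other 4. It added up to 4 members per list and comparison with the largest changes, and a short set of genes named in every comparison, of which 4 are not reported here. Chromosome and gene order came from the RefSeq annotation of GRCh38.p14 for 9524 genes, and start positions served only to order the genes.

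The procedure from quantile normalization on was tested on simulated data built from the levels of 15765 probes, already background-corrected and filtered. Background correction and the detection filter were not simulated, so the recovered values do not show how those steps affect fold changes or 2-fold counts. For Dox1000 versus Ramos 37 of 64 genes (57.8%) planted at a log2 change of 0.5 were recovered, 62 of 64 (96.9%) at 1 and 63 of 64 (98.4%) at 2, with median fitted changes of 0.49, 0.98 and 1.97. Of 8784 unchanged genes 10 passed, 1 of them at 2-fold. A planted shift of the lysosome list gave camera adjusted p = 5.52e-32, and 1 of 189 tests of unchanged lists passed. The simulated noise was independent between probes, so these values do not show how correlation between genes affects the list tests. Alternatives were no background correction, median scaling, the deposited log2 values, no filter, detection on all 24 arrays, the mean over probes, no fold floor, an adjusted p under 0.01, an intensity trend, only the 8 arrays compared, the replicate number as a block, and each array left out in turn. Lists were also tested without genes of chromosomes 12 and 20, and the genes around ABCB1 without ABCB1 and ABCB4, alternatives chosen after the data were seen.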

Results

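Ramos, a cell line from human Burkitt lymphoma (a tumour of germinal centre B cells), and 5 derivatives selected for growth in doxorubicin were profiled on bead arrays. Doxorubicin is an anthracycline that traps topoisomerase II on DNA. The derivatives, Dox100, Dox250, Dox500, Dox750 and Dox1000, grew in 100, 250, 500, 750 and 1000 nM of the drug, each raised from the one before it. Each line was measured on 4 arrays, from 4 cultures split from 1 culture, so p-values measure only the spread between these split cultures, which may be technical. The resistant lines were harvested with the drug in the medium and Ramos without it. Median signal ran from 121.1 to 163.4 per array, and 14158 to 15564 of the 47323 probes were detected. The number of arrays limits the precision of the values below. They are log2 fold changes ± SE from limma (n = 4 per line) over 9533 genes. The comparisons ask what each line carries relative to Ramos, and how each line differs from the one before it. Counts of genes at least 2-fold different use fitted values, also for probes undetected in a line, where a bound of 2-fold is not always reached.

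ABCB1, which encodes the drug efflux pump P-glycoprotein, was undetected on all 4 Ramos arrays and detected on every array from Dox250 on. In Dox100 it was detected on 1 of 4 arrays, and its difference from Ramos did not pass the test (0.31 ± 0.16, adjusted p = 0.121), with its other probe differing in sign. With 1 array left out it ran from 0.08 without Dox100 replicate 3 to 0.43 without Ramos replicate 1, and only the latter passed (adjusted p = 0.0394). ABCB1 was at least 16.3-fold higher than in Ramos in Dox250, at least 54.0-fold in Dox500, at least 50.4-fold in Dox750 and at least 55.6-fold in Dox1000 (adjusted p = 9.98e-20 in Dox1000). It rose by 4.58 ± 0.16 from Dox100 to Dox250 and by 1.73 ± 0.16 from Dox250 to Dox500 (adjusted p = 2.02e-15 and 1.07e-07). Its differences of -0.10 and 0.14 at the last 2 steps did not pass (adjusted p = 0.764 and 0.58). Its neighbour ABCB4, a phospholipid translocator of the same family, was already 2.41 ± 0.13 higher in Dox100. ABCB4 stood at 1.89, 1.46, 2.31 and 3.26 above Ramos in the later lines (SE 0.13), and 2 of 4 Ramos arrays detected it.

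**Figure D1:**
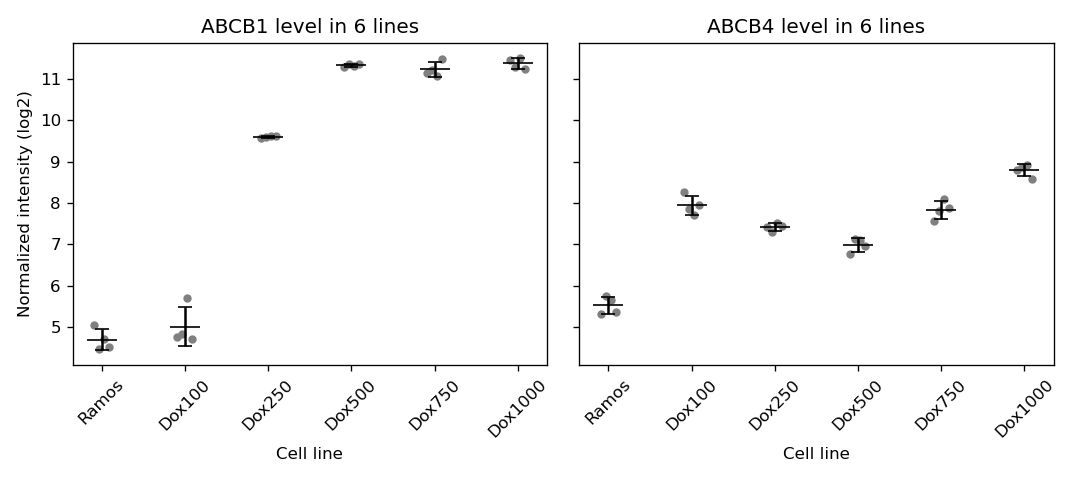
Normalized log2 intensity of ABCB1 and ABCB4 on each array of the 6 lines (grey points), with the mean of the 4 arrays (bar) and its SD (whiskers). Mean ABCB1 was 4.70 in Ramos, 5.01 in Dox100, where 1 array lay at 5.72, and 9.59 in Dox250, while ABCB4 was higher than in Ramos from Dox100 on.

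The topoisomerase II genes, whose products doxorubicin poisons, fell in every resistant line. TOP2A differed from Ramos in the 5 lines in order of dose by -0.76, -0.78, -0.69, -0.76 and -0.52 (SE 0.09), and TOP2B by -0.57, -0.57, -0.52, -0.59 and -0.41 (SE 0.08), with adjusted p of at most 8.29e-05 in limma. BCL2, an inhibitor of apoptosis that was detected on 1 of 4 Ramos arrays, rose by 1.17, 1.17, 1.07, 1.22 and 1.92 (SE 0.16). MS4A1, the B cell antigen targeted by rituximab, rose by 0.83, 1.01, 0.78, 1.01 and 0.80 (SE 0.10), although its other probe differed in sign in Dox500. MYC, which the Burkitt translocation drives, fell by 0.34 ± 0.08 in Dox100 (adjusted p = 0.0019). It did not pass in Dox250, Dox500 or Dox750, at -0.03, -0.06 and -0.12 (adjusted p = 0.832, 0.556 and 0.249). In Dox1000 MYC did not pass either (-0.20 ± 0.08, adjusted p = 0.0521), but did without Dox1000 replicate 2 (-0.25, adjusted p = 0.0187).

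Dox1000, the end of the lineage, had 576 genes at least 2-fold higher than Ramos and 324 lower, and 5460 genes (57.3%) passed the limma test. Of these calls 119 higher and 33 lower rest on a probe undetected in a line, with a bound under 2-fold or none. S100A4, a calcium-binding protein linked to cell motility, rose by 6.82 ± 0.08, and HAVCR2, an inhibitory immune receptor, by 5.80 ± 0.10. The bile acid carrier FABP6 was undetected in Ramos and at least 41.5-fold higher in Dox1000. So were NLRP11 (at least 47.4-fold), the disulfide isomerase AGR2 (at least 39.9-fold), CCDC85A (at least 28.7-fold) and the cholinesterase BCHE (at least 32.0-fold). SNCAIP, which encodes synphilin and was detected on 1 of 4 Ramos arrays, rose by 5.52 ± 0.12. IFI44L was higher (adjusted p = 2.19e-15), with no fold given because the probe read was undetected on all Ramos arrays while another was detected. The palmitoyltransferase gene ZDHHC8 fell by 6.31 ± 0.17 (detected on 3 of 4 Dox1000 arrays) and HENMT1, a methyltransferase of small germline RNAs, by 4.88 ± 0.21 (detected on 1 of 4). ANXA2, a phospholipid-binding annexin, fell by 4.60 ± 0.21 and NLRP7 by 4.0 ± 0.13. PIGY, of glycolipid anchor synthesis, was at least 9.58-fold lower, TEX30 at least 9.83-fold, STOX2 at least 13.4-fold, ZNF275 at least 6.94-fold, TESC at least 6.71-fold and ADAM23 at least 7.03-fold. The highest adjusted p among these genes was 3.89e-14.

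Interferon-stimulated genes and NF-kB targets had the highest medians of the lists in Dox1000. Of 23 interferon-stimulated genes 21 rose and 1 fell (21 and 1 adjusted over the list alone). Their median was 2.17, or 1.66 with the 7 genes undetected in 1 line at their bound (camera adjusted p = 1.99e-13, and adjusted p = 0.0337 with an estimated correlation). IFI44 was at least 36.0-fold higher, EPSTI1 at least 11.0-fold and IFI27 at least 10.1-fold. Of 18 NF-kB targets 16 rose and 1 fell (17 and 1 adjusted over the list alone). Their median was 1.06, or 1.0 at bounds (camera adjusted p = 1.26e-06, and adjusted p = 0.0337 with an estimated correlation). Among them were the lymphotoxin genes LTB (2.34 ± 0.09) and LTA (2.17 ± 0.13), the receptor CD40 (1.91 ± 0.12) and IER3 (1.72 ± 0.19, detected on 2 of 4 Ramos arrays).

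Antigen presentation and lysosome genes rose with them. In MHC class I 9 of 14 genes rose and 1 fell (9 and 1 adjusted over the list alone), with a median of 0.50. HLA-F rose by 1.57 ± 0.07 and HLA-B by 1.21 ± 0.08. In MHC class II 9 of 11 rose and 0 fell (9 and 0 adjusted over the list alone), with a median of 0.52, or 0.45 at bounds. HLA-DOB rose by 1.01 ± 0.10, and HLA-DQB1 was at least 1.84-fold higher. Of 25 lysosome genes 17 rose and 1 fell (17 and 3 adjusted over the list alone), with a median of 0.35. Progranulin GRN (1.88 ± 0.09), CTSZ (1.30 ± 0.10) and NPC2 (1.26 ± 0.07) were among them. Camera gave adjusted p = 0.00171, 0.00214 and 0.000258 for these 3 lists, and adjusted p = 0.0337, 0.0405 and 0.0337 with an estimated correlation.

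Genes of growth and of stress moved in Dox1000 too. In ribosome biogenesis and MYC targets 1 of 29 rose and 17 fell (1 and 17 adjusted over the list alone), with a median of -0.37, or -0.38 at bounds (camera adjusted p = 0.00052, and adjusted p = 0.00907 with an estimated correlation). NOLC1, a nucleolar chaperone, fell by 1.62 ± 0.09 and POLR1B, of RNA polymerase I, by 0.92 ± 0.12. Of 6 efflux transporters 4 rose and 0 fell (5 and 0 adjusted over the list alone), with a median of 0.46 (camera adjusted p = 0.016, and adjusted p = 0.0405 with an estimated correlation). The efflux list holds ABCB1 and ABCB4, whose large rises are given above, and was not tested without them in any comparison. Of 22 genes of the ATF4 and amino acid response 15 rose and 0 fell (16 and 0 adjusted over the list alone), with a median of 0.44. ATF3 rose by 2.47 ± 0.14 and DDIT3 by 1.75 ± 0.11. That list passed with the preset correlation (camera adjusted p = 3.77e-05), but had adjusted p = 0.0957 with an estimated correlation.

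The other lists that passed did so only with the preset correlation. In DNA replication 5 of 30 rose and 15 fell (5 and 16 adjusted over the list alone), with a median of -0.24 and MCM5 at -0.89 ± 0.07. In double-strand break repair 1 of 20 rose and 11 fell (1 and 11 adjusted over the list alone), with a median of -0.27. The damage marker gene H2AX fell by 0.90 ± 0.12 and TP53BP1 by 0.83 ± 0.10. In heat shock proteins 1 of 13 rose and 9 fell (1 and 9 adjusted over the list alone), with a median of -0.37 and HSPA8 at -1.01 ± 0.09. In plasma cell genes 8 of 13 rose and 2 fell (8 and 2 adjusted over the list alone), with a median of 0.45 and CD27 up by 1.25 ± 0.06. The camera test gave adjusted p = 0.0192, 0.0484, 0.0114 and 0.0437 for these lists in turn, and adjusted p = 0.163, 0.0846, 0.163 and 0.103 with an estimated correlation. The double-strand break call ended without Ramos replicate 4, Dox1000 replicate 2 or Dox1000 replicate 4 (adjusted p = 0.0523, 0.0505 and 0.0889), and the plasma cell call without Ramos replicate 1 (0.0503).

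The remaining lists did not pass in Dox1000 against Ramos, though single members changed. Of 8 genes of anthracycline targets and metabolism 3 rose and 4 fell (4 and 4 adjusted over the list alone, camera adjusted p = 0.974). Their median of -0.10 and mean of 0.30 differed in sign. The aldehyde dehydrogenase ALDH1A1 rose by 4.08 ± 0.10 from 1 of 4 detected Ramos arrays, and the DNA repair phosphodiesterase TDP1 fell by 1.09 ± 0.13. Among 22 p53 targets 7 rose and 6 fell (8 and 6 adjusted over the list alone, camera adjusted p = 0.388), with PMAIP1 up by 1.25 ± 0.18 and CDKN1A at least 1.67-fold higher. Of 16 pro-apoptotic genes 6 rose and 3 fell (6 and 3 adjusted over the list alone, camera adjusted p = 0.152). BMF rose by 2.25 ± 0.18 from 1 of 4 detected Ramos arrays, HRK by 1.92 ± 0.15 and BCL2L11 by 1.65 ± 0.11. Of 8 anti-apoptotic genes 4 rose and 0 fell (4 and 0 adjusted over the list alone, camera adjusted p = 0.111).

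B cell identity genes split in Dox1000, with 7 of 20 up and 8 down (8 and 8 adjusted over the list alone, camera adjusted p = 0.796). VPREB3 rose by 1.54 ± 0.06, and CD24 was at least 3.65-fold lower. Of 20 germinal centre genes 5 rose and 8 fell (5 and 10 adjusted over the list alone, camera adjusted p = 0.378), with LMO2 up by 1.54 ± 0.10 and MEF2C at -1.50 ± 0.19. Of 24 glutathione and NRF2 targets 12 rose and 5 fell (12 and 6 adjusted over the list alone, camera adjusted p = 0.187), and the glutathione transferase MGST1 rose by 1.60 ± 0.09. Of 26 glycolysis and hypoxia genes 7 rose and 11 fell (7 and 11 adjusted over the list alone, camera adjusted p = 0.568). Their median of -0.21 and mean of 0.12 differed in sign, and SLC2A3, a glucose transporter, was at least 6.69-fold higher. The mitotic list had 12 of 28 up and 3 down (12 and 5 adjusted over the list alone, camera adjusted p = 0.279). Endoplasmic reticulum chaperones had 8 of 20 up and 2 down (8 and 3 adjusted over the list alone, camera adjusted p = 0.281). Cholesterol synthesis had 8 of 18 up and 4 down (8 and 4 adjusted over the list alone, camera adjusted p = 0.708). Oxidative phosphorylation had 9 of 27 up and 5 down (9 and 5 adjusted over the list alone, camera adjusted p = 0.568).

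Around ABCB1 on chromosome 7, 6 of 11 genes rose and 1 fell in Dox1000 (6 and 1 adjusted over the list alone, median 0.34, camera adjusted p = 0.0626), and ELAPOR2 rose by 1.30 ± 0.06. The list holds ABCB1 and ABCB4 themselves. Among the other 9 genes 4 rose and 1 fell, with a median of -0.10 but an upward test (camera adjusted p = 0.568), an alternative chosen after the results were seen. The whole list passed without Ramos replicate 2 or 3 (camera adjusted p = 0.0458 and 0.0486). Markers of other cell types were mixed. T and NK cell markers had 4 of 7 up and 1 down (4 and 2 adjusted over the list alone, camera adjusted p = 0.171). Their median was 0.72, or 0 with the 3 genes undetected in 1 line at their bound, and PRF1 was at least 2.33-fold and NKG7 at least 1.84-fold higher. Myeloid markers had 2 of 5 up and 1 down (2 and 1 adjusted over the list alone, camera adjusted p = 0.725), with a median of -0.19, a mean of 0.38 and an upward test. CST3 was at least 3.41-fold higher. Of 3 epithelial and stromal markers, too few to test, DCN was at least 3.73-fold higher.

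By gene order in GRCh38.p14, genes of chromosomes 12 and 20 stood above the rest in Dox1000, with medians of 0.43 over 532 genes and 0.41 over 284 (camera adjusted p = 1.02e-15 and 1.93e-12). Genes of chromosome 7 stood below, with a median of -0.25 over 471 genes, of which 79 rose and 229 fell (camera adjusted p = 0.000988). Its medians were -0.20, -0.23 and -0.23 in Dox250, Dox500 and Dox750 (camera adjusted p = 0.000427, 3.06e-05 and 0.000304), while in Dox100 it did not pass (-0.03, camera adjusted p = 0.486). These calls held with an estimated correlation, and of the 23 chromosomes tested no other passed in Dox250, Dox500, Dox750 or Dox1000. In Dox100 chromosome 13 passed (median -0.23, camera adjusted p = 0.00152), but had adjusted p = 0.174 with an estimated correlation. Of the genes named for Dox1000, CD40, CTSZ and CST3 lie on chromosome 20. DDIT3, CD27, HRK, MGST1, SLC2A3, DCN and TESC lie on chromosome 12. Without genes of chromosomes 12 and 20 the plasma cell and double-strand break repair lists did not pass (camera adjusted p = 0.158 and 0.0952) and the genes around ABCB1 did (camera adjusted p = 0.0316), a test chosen after the data were seen. In Dox1000 209 genes were at least 2-fold higher and 85 lower without background correction, and 219 and 92 in the authors' deposited log2 values. Among probes detected on all 24 arrays the counts were 283 and 183.

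Dox100, the first resistant line, already had 427 genes at least 2-fold higher than Ramos and 255 lower, with 4418 genes (46.3%) passing. HAVCR2 rose by 5.63 ± 0.10 and S100A4 by 5.26 ± 0.08, with FABP6 at least 18.9-fold, CCDC85A at least 16.9-fold and the phosphatidylserine receptor TIMD4 at least 17.8-fold higher. NLRP7 fell by 4.33 ± 0.13, and HENMT1 was at least 21.6-fold, STOX2 at least 13.1-fold and PIGY at least 9.32-fold lower. NLGN4X, a synaptic adhesion gene, was lower (adjusted p = 2.18e-21), with no fold given because the probe read was undetected in Dox100 while another was detected. Of 23 interferon-stimulated genes 20 rose and 1 fell, with a median of 1.88, or 1.46 at bounds. Of 18 NF-kB targets 15 rose and 1 fell, with a median of 1.38, or 1.35 at bounds. Both pairs of counts were the same adjusted over the list alone. By camera the lists had adjusted p = 1.74e-12 and 4.75e-09, and adjusted p = 0.036 and 0.0175 with an estimated correlation. The adhesion receptor CD44 was at least 8.05-fold higher and LTB rose by 2.83 ± 0.09, while IFITM2 fell by 2.92 ± 0.14 to detection on 1 of 4 arrays.

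In the same line 8 of 11 MHC class II genes rose and 0 fell (the same adjusted over the list alone), with a median of 0.64, or 0.56 at bounds. In MHC class I 10 of 14 rose and 2 fell (the same adjusted over the list alone), with a median of 0.51. Of 25 lysosome genes 16 rose and 1 fell (17 and 2 adjusted over the list alone), with a median of 0.47 and GRN up by 1.93 ± 0.09. Of 20 endoplasmic reticulum chaperones 10 rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 0.21 and HSPA5 up by 0.74 ± 0.09. Of 20 germinal centre genes 3 rose and 11 fell (the same adjusted over the list alone), with a median of -0.27. MEF2C fell by 1.27 ± 0.19 and BACH2 by 1.07 ± 0.09. Camera gave adjusted p = 0.000476, 0.0018, 1.56e-05, 0.00813 and 0.0258 for these 5 lists, and adjusted p = 0.0343, 0.036, 0.0176, 0.036 and 0.036 with an estimated correlation.

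Another 4 lists passed in Dox100 only with the preset correlation. Of 6 efflux transporters 4 rose and 0 fell (5 and 0 adjusted over the list alone), and of 13 plasma cell genes 8 rose and 2 fell (9 and 2 adjusted over the list alone). The efflux list holds ABCB1 and ABCB4 and was not tested without them. Of 24 glutathione and NRF2 targets 13 rose and 3 fell (the same adjusted over the list alone). In the ATF4 list 3 of 22 rose and 11 fell (3 and 12 adjusted over the list alone), with STC2, a stanniocalcin, at -1.31 ± 0.11. The medians were 0.43, 0.41, 0.22 (0.17 at bounds) and -0.29 (-0.30 at bounds). The camera test gave adjusted p = 0.0327, 0.0258, 0.0491 and 0.0348, and adjusted p = 0.0599, 0.0694, 0.132 and 0.393 with an estimated correlation. Dox100 counts were 139 and 63 without background correction, 153 and 66 in the deposited values, and 210 and 126 among probes detected on all 24 arrays.

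Dox250, Dox500 and Dox750 kept S100A4, HAVCR2 and FABP6 among the 5 most raised genes named for each. Against Ramos, 413 genes were at least 2-fold higher and 302 lower in Dox250, 373 and 310 in Dox500, and 459 and 398 in Dox750. The genes passing numbered 4707 (49.4%), 4616 (48.4%) and 5022 (52.7%). S100A4 stood 5.20, 5.97 and 6.01 above Ramos (SE 0.08) and HAVCR2 5.88, 5.69 and 5.89 (SE 0.10). FABP6 was at least 24.5-fold, 23.2-fold and 30.2-fold higher. CCDC85A was at least 24.5-fold and CNTNAP4, a neurexin relative, at least 16.8-fold higher in Dox250. NLRP11 was at least 31.4-fold higher in Dox500 and IFI44 at least 44.2-fold in Dox750. ZDHHC8 differed by -6.37, -5.77 and -6.35 (SE 0.17), NLRP7 by -5.55, -4.59 and -5.33 (SE 0.13) and ANXA2 by -4.58, -4.86 and -4.61 (SE 0.21). ANXA2 was detected on 2, 1 and 1 of the 4 arrays of these lines, ZDHHC8 on 2, 4 and 2, and NLRP7 on 2, 4 and 3. HENMT1 was at least 20.2-fold, 20.6-fold and 20.1-fold lower. STOX2 was at least 12.3-fold lower in Dox250, and PIGY at least 8.90-fold and 8.67-fold lower in Dox500 and Dox750.

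Interferon-stimulated genes stayed above Ramos in these 3 lines, with medians of 1.53, 0.91 and 2.28 (1.12, 0.89 and 1.83 at bounds). Of the 23, 21, 17 and 21 rose and 1 fell in each line, the same adjusted over the list alone. By camera this list had adjusted p = 9.59e-12, 2e-07 and 7.34e-15, and adjusted p = 0.0491, 0.217 and 0.0548 with an estimated correlation. NF-kB targets had medians of 1.04, 0.68 and 0.70 (0.89, 0.69 and 0.82 at bounds). Of the 18, 15, 14 and 14 rose and 1, 2 and 2 fell, the same adjusted over the list alone. Camera gave adjusted p = 7.75e-07, 0.000522 and 0.000529, and adjusted p = 0.0303, 0.217 and 0.0758 with an estimated correlation. Lysosome genes had medians of 0.46, 0.46 and 0.54. Of the 25, 17, 17 and 19 rose and 1, 2 and 1 fell, the same adjusted over the list alone. The camera test gave adjusted p = 4.26e-05, 0.000143 and 1.59e-05, and adjusted p = 0.0303, 0.0687 and 0.0306 with an estimated correlation.

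In Dox250 4 of 6 efflux transporters rose and 0 fell (5 and 0 adjusted over the list alone), and 13 of 20 endoplasmic reticulum chaperones rose and 1 fell (15 and 1 adjusted over the list alone). By camera the lists had adjusted p = 0.0141 and 0.013, and adjusted p = 0.0491 for both with an estimated correlation. ABCB1 and ABCB4, both higher in Dox250, are among the efflux transporters. In MHC class II 6 of 11 rose and 0 fell, in MHC class I 8 of 14 rose and 1 fell, and in plasma cell genes 8 of 13 rose and 2 fell. Adjusted over the list alone these counts were the same, but for 2 class I genes that fell. These 3 lists passed only with the preset correlation (camera adjusted p = 0.0141, 0.0291 and 0.0422), with adjusted p = 0.107, 0.112 and 0.112 with an estimated correlation.

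In Dox750 4 of 6 efflux transporters, 9 of 14 MHC class I genes and 8 of 11 MHC class II genes rose, and 0, 1 and 0 fell. ABCB1 and ABCB4 are again among those transporters. Of 16 pro-apoptotic genes 7 rose and 1 fell, of 20 germinal centre genes 3 rose and 11 fell, and of 22 ATF4 genes 3 rose and 13 fell. Adjusted over the list alone 10 class I and 9 class II genes rose, and the other counts were the same. Camera with the preset correlation gave adjusted p = 0.0223, 0.0166, 0.0223, 0.0473, 0.0473 and 0.0219. The 6 calls were lost with adjusted p = 0.0758, 0.0758, 0.128, 0.246, 0.0758 and 0.272 with an estimated correlation. Without background correction 139 genes were at least 2-fold higher and 79 lower in Dox250, 107 and 74 in Dox500, and 152 and 126 in Dox750. In the deposited values the counts were 147 and 90, 118 and 79, and 161 and 139, and among probes detected on all 24 arrays 219 and 151, 190 and 153, and 236 and 226.

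**Figure D2:**
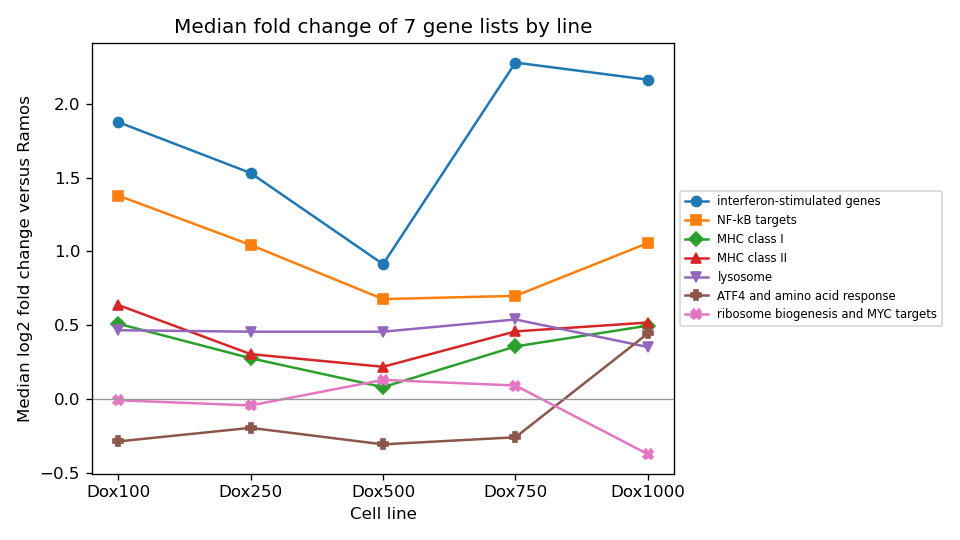
Median log2 fold change against Ramos of the measured genes of 7 lists (1 line each) in the 5 resistant lines. The interferon-stimulated median ran from 1.88 in Dox100 to 0.91 in Dox500, 2.28 in Dox750 and 2.17 in Dox1000, and from Dox750 to Dox1000 the ATF4 median went from -0.26 to 0.44 and the ribosome biogenesis median from 0.09 to -0.37.

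The genes called in Dox1000 were followed back through the lineage. Of its 576 higher genes, 205 (35.6%) were called at least 2-fold higher in all 5 lines, 42 held from Dox250, 37 from Dox500 and 101 from Dox750. The other 191 (33.2%) were called in Dox1000 but not in Dox750. Only 69 genes were at least 2-fold higher in Dox1000 than in Dox750, so most of the 191 crossed the threshold by smaller changes. Of the 324 lower genes, 135 (41.7%) held from Dox100, 45 from Dox250, 18 from Dox500, 53 from Dox750 and 73 (22.5%) from Dox1000. Dox100 and Dox1000 shared 321 higher and 158 lower calls, some of them not called in a line between. Independent lists of these sizes would share 25.8 and 8.67. In 100 simulations of unchanged lines against the shared Ramos arrays the overlap was 0, a value fixed by the near absence of 2-fold calls in such lines, which says nothing of how shared arrays raise the overlap of long lists. With the Ramos arrays split 2 and 2 between the comparisons, the 6 splits gave 310 to 324 and 144 to 153 shared calls. Genes held from Dox100 numbered 63 higher and 25 lower without background correction, 71 and 28 in the deposited values, and 98 and 48 among probes detected on all 24 arrays.

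From Dox100 to Dox250 ABCB1 rose by 4.58 ± 0.16, and the adhesion molecule CADM1 by 2.86 ± 0.15, both detected on 1 of 4 Dox100 arrays. CADM1 had a mean level of 8.90 in Ramos, 5.36 in Dox100 and 8.22 in Dox250, so that its rise brought it near the Ramos level. NLGN4X was higher (adjusted p = 5.72e-18), with its read probe undetected in Dox100 and at 8.90 in Dox250, against 10.0 in Ramos. PHACTR3 was at least 3.15-fold and GAPT at least 3.11-fold higher. TEX30 fell by 3.46 ± 0.15 (detected on 1 of 4 Dox250 arrays), COBLL1 by 3.41 ± 0.10, ZDHHC8 by 3.32 ± 0.17 (detected on 2 of 4) and CD44 by 2.53 ± 0.14, and the embryonic globin HBE1 was at least 3.21-fold lower. CD44 and HBE1 were undetected in Ramos. CDKN1A, which encodes a cell cycle inhibitor, fell by 1.40 ± 0.21 (detected on 3 of 4 Dox250 arrays), and ABCB4 by 0.52 ± 0.13 (adjusted p = 0.00868). MYC rose by 0.32 ± 0.08 (adjusted p = 0.0144), a call lost without Dox100 replicate 1, Dox100 replicate 3 or Dox250 replicate 3 (adjusted p = 0.0687, 0.0506 and 0.0574). The 245 measured genes beyond ABCB1 on chromosome 7 had a median of -0.43, with 131 having fallen and 11 risen, and the 225 before it a median of 0.00. Of 22 ATF4 genes 7 rose and 0 fell (the same adjusted over the list alone), with a median of 0.14 (camera adjusted p = 0.0317), but with adjusted p = 0.481 with an estimated correlation. No other list passed. At this step 38 genes were at least 2-fold higher and 63 lower (37.6% higher), and 1283 passed. Without background correction the counts were 13 and 9 (59.1%), in the deposited values 13 and 12 (52%), and among probes detected on all 24 arrays 11 and 19.

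From Dox250 to Dox500 ABCB1 rose by 1.73 ± 0.16, and the 3 other genes of the list around it that rose all lie on the ABCB4 side. TMEM243 rose by 0.86 ± 0.11, ELAPOR2 by 0.83 ± 0.06 and CROT, a carnitine transferase, by 0.75 ± 0.11. Of 11 genes around ABCB1 4 rose and 1 fell (4 and 3 adjusted over the list alone), with a median of 0.20 (camera adjusted p = 0.0265, and adjusted p = 0.0592 with an estimated correlation). Without ABCB1 and ABCB4, 3 of 9 rose and 0 fell (camera adjusted p = 0.0358, and adjusted p = 0.189 with an estimated correlation). The 4 genes of the list on its other side did not pass, among them SLC25A40 at -0.33 and SRI at -0.41 (adjusted p = 0.0987 and 0.063). ABCB4, next to ABCB1, fell by 0.43 ± 0.13 (adjusted p = 0.0262), a call lost without Dox250 replicate 3 or 4 or Dox500 replicate 1 or 4 (adjusted p = 0.0783, 0.054, 0.078 and 0.0565). FGD5 was at least 2.43-fold and the gluconeogenesis enzyme FBP1 at least 2.69-fold higher. NLRP11 rose by 2.16 ± 0.11, AFAP1-AS1 by 1.92 ± 0.13 (detected on 3 of 4 Dox250 arrays) and SNAR-A1 by 1.97 ± 0.41 (detected on 1 of 4). PCP4 fell by 3.20 ± 0.11, ASZ1 by 2.85 ± 0.16 and the actin nucleator COBL by 2.75 ± 0.19 (detected on 1 of 4 Dox500 arrays). The tetraspanin CD9 was lower (adjusted p = 4.69e-09), with its read probe undetected in Dox500, and PRODH, of proline breakdown, was at least 2.02-fold lower. The probes read for these 5 genes were undetected in Ramos.

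Immune lists fell at this step. Of 18 NF-kB targets 0 rose and 9 fell (0 and 10 adjusted over the list alone), with a median of -0.30, or -0.27 at bounds, and LTA at -0.77 ± 0.13. Of 11 MHC class II genes 0 rose and 5 fell (the same adjusted over the list alone), with a median of -0.27 and HLA-DQB1 at -1.21 ± 0.14 (detected on 2 of 4 Dox500 arrays). Of 14 MHC class I genes 0 rose and 6 fell (0 and 7 adjusted over the list alone), with a median of -0.17, or -0.27 at bounds, and HLA-F at -0.54 ± 0.07. Of 18 cholesterol synthesis genes 0 rose and 5 fell (0 and 6 adjusted over the list alone), with a median of -0.19. INSIG1, a sterol sensor, fell by 0.98 ± 0.11. It lies in a block of 71 genes at the end of chromosome 7 with a median of -0.39, found by scanning the changes of this step. Camera gave adjusted p = 2.14e-06, 0.00032, 0.00275 and 0.000688 for these 4 lists, and adjusted p = 0.0264, 0.0264, 0.0488 and 0.0144 with an estimated correlation.

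Other lists passed from Dox250 to Dox500 only with the preset correlation. Of 23 interferon-stimulated genes 2 rose and 13 fell (2 and 16 adjusted over the list alone), with a median of -0.42, or -0.39 at bounds. IFI27 rose by 1.19 ± 0.20 while MX1 fell by 0.90 ± 0.16. Of 20 B cell identity genes 1 rose and 4 fell, of 22 ATF4 genes 0 rose and 4 fell, and of 26 glycolysis genes 1 rose and 5 fell (1 and 4, 1 and 5, and 1 and 5 adjusted over the list alone). The camera test gave adjusted p = 2.14e-06, 0.0357, 0.0149 and 0.0357 for these lists, and adjusted p = 0.19, 0.19, 0.337 and 0.385 with an estimated correlation. At this step 40 genes were at least 2-fold higher and 31 lower (56.3% higher), and 1398 passed. Without background correction and in the deposited values 6 were higher and 3 lower (66.7% in both), and among probes detected on all 24 arrays 11 and 8.

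From Dox500 to Dox750 interferon-stimulated genes rose, after a fall that passed only with the preset correlation. Both steps share the Dox500 arrays, so low values in Dox500 alone would give a fall and then a rise. The same holds for the MHC and cholesterol lists below. Of 23 interferon-stimulated genes 18 rose and 0 fell (21 and 0 adjusted over the list alone), with a median of 1.06 (camera adjusted p = 3.48e-31, and adjusted p = 0.00395 with an estimated correlation). The antiviral genes IFIT1 (2.46 ± 0.19), IFI6 (1.81 ± 0.10) and IFIT3 (at least 3.22-fold) were among them. The inflammatory caspase CASP1 was at least 2.33-fold and CHI3L2, a chitinase relative, at least 2.73-fold higher. FBP1, raised at the step before, was at least 2.68-fold lower. TACC2 was at least 1.29-fold, HOPX at least 1.23-fold and SPATA13 at least 1.77-fold lower, and NYNRIN fell by 1.04 ± 0.11. ABCB4 rose by 0.85 ± 0.13 (adjusted p = 0.00016) while ABCB1 differed by -0.10 ± 0.16 (adjusted p = 0.764).

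At this step 4 of 11 MHC class II genes rose and 0 fell (5 and 0 adjusted over the list alone), with a median of 0.32. In MHC class I 5 of 14 rose and 1 fell (6 and 1 adjusted over the list alone), with a median of 0.19. TAP1, which supplies peptides to class I, rose by 0.73 ± 0.08. Of 18 cholesterol synthesis genes 6 rose and 0 fell (6 and 1 adjusted over the list alone), with a median of 0.21 and INSIG1 up by 0.51 ± 0.11. Of 20 germinal centre genes 1 rose and 5 fell (2 and 8 adjusted over the list alone), with a median of -0.14 and BACH2 at -0.56 ± 0.09. By camera the lists had adjusted p = 0.000108, 0.000377, 0.000943 and 0.00212, and adjusted p = 0.0104, 0.0118, 0.00866 and 0.0101 with an estimated correlation. Of 24 glutathione and NRF2 targets 2 rose and 0 fell, of 25 lysosome genes 2 rose and 0 fell, and of 22 ATF4 genes 0 rose and 3 fell (2 and 0, 3 and 0, and 0 and 4 adjusted over the list alone). These passed with the preset correlation (camera adjusted p = 0.00751, 0.0477 and 0.0477), but had adjusted p = 0.0546, 0.2 and 0.447 with an estimated correlation. In all 31 genes were at least 2-fold higher and 4 lower by fitted values (88.6% higher), and 762 passed. Of the 4 lower genes TACC2 and HOPX have bounds under 2-fold, and 4 of the 31 higher genes have a bound under 2-fold or none. In limma without background correction and in the deposited values 4 were higher and 0 lower (100% higher), and among probes detected on all 24 arrays 6 and 0. Those counts of lower genes were 0 at an unadjusted p under 0.05 as well, although 547, 543 and 405 genes passed in the lower direction with no fold floor.

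From Dox750 to Dox1000 the ATF4 and amino acid response rose, with 21 of 22 genes higher and 0 lower (the same adjusted over the list alone). The median was 0.92, or 0.83 at bounds (camera adjusted p = 1.44e-26, and adjusted p = 0.000469 with an estimated correlation). STC2 rose by 2.37 ± 0.11, CHAC1, which degrades glutathione, by 2.29 ± 0.17 and DDIT4, an inhibitor of mTOR signalling, by 1.83 ± 0.17. ATF3 rose by 1.83 ± 0.14 and INHBE, an activin subunit, by 2.44 ± 0.11. Of 29 ribosome biogenesis genes and MYC targets 0 rose and 25 fell (0 and 26 adjusted over the list alone), with a median of -0.36 (camera adjusted p = 2.61e-14, and adjusted p = 1.19e-06 with an estimated correlation). POLR1B fell by 0.77 ± 0.12, NOP16 by 0.72 ± 0.07 and RRP12 by 0.70 ± 0.08. MYC itself differed by -0.08 ± 0.08 and did not pass (adjusted p = 0.565). MYBBP1A, a nucleolar protein, fell by 1.18 ± 0.17, PCP4 by 1.14 ± 0.11 and POP1, of the RNase MRP complex, by 1.11 ± 0.10. GALR2 (detected on 2 of 4 Dox1000 arrays) fell by 1.10 ± 0.17 and GPRIN1 by 1.06 ± 0.13.

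BCL2 rose at this last step by 0.70 ± 0.16 (adjusted p = 0.0037) and ABCB4 by 0.95 ± 0.13 (adjusted p = 1.31e-05). LMO2 rose by 1.49 ± 0.10, TP53INP1 by 1.44 ± 0.10 and SESN2 by 1.13 ± 0.17. TOP2A, at 0.24 ± 0.09, did not pass (adjusted p = 0.0512), but did without Dox1000 replicate 2 (0.32, adjusted p = 0.00964) or Dox750 replicate 3 (0.27, adjusted p = 0.0485). MS4A1, at -0.21 ± 0.10 (adjusted p = 0.133), passed without Dox1000 replicate 4 (-0.29, adjusted p = 0.0386), and its other probe differed in sign. Of 13 heat shock proteins 0 rose and 8 fell (1 and 10 adjusted over the list alone), with a median of -0.36, or -0.41 at bounds, and HSPA8 at -0.83 ± 0.09. Of 18 NF-kB targets 5 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 0.27, or 0.26 at bounds, and CD44 at least 1.74-fold higher. Of 8 anti-apoptotic genes 5 rose and 0 fell (the same adjusted over the list alone), with a median of 0.30 and CFLAR up by 0.70 ± 0.13. These 3 lists passed with the preset correlation (camera adjusted p = 8.92e-05, 0.00156 and 0.0129), but had adjusted p = 0.0789, 0.102 and 0.0789 with an estimated correlation. In all 69 genes were at least 2-fold higher and 8 lower (89.6% higher), and 2261 passed. In limma without background correction and in the deposited values 16 were higher and 0 lower (100% higher). The 0 stood at an unadjusted p under 0.05 as well, although 1212 and 1203 genes passed in the lower direction with no fold floor. Among probes detected on all 24 arrays the counts were 36 and 4, and median scaling gave 4 lower genes.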

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

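No test in this part was chosen after its result was seen. In each line the 4 values of 26 genes and 3 array measures were searched for an array far from the others, by its gap to the nearest array over the range of the 4, against Dixon's critical value. Of 174 groups 9 held such an array (5.17%), and chance flags about 1 in 20 groups. ABCB1 was at 5.72 on Dox100 replicate 3, above the other Dox100 arrays (4.73 to 4.84), and TOP2B at 11.5 on Dox100 replicate 1, below the others (11.6 to 11.7). HAVCR2 was at 11.6 on Dox250 replicate 3, below the others (11.7). In Dox500 replicate 4 PIGY was at 4.5, above the other arrays (4.46), and STOX2 at 4.64, below them (5.04 to 5.13). In Dox750 HENMT1 was at 5.36 on replicate 2 (others 4.69 to 4.81) and ANXA2 at 6.31 on replicate 1 (others 5.54 to 5.66), above the other arrays, and NLRP7 was at 5.6 on replicate 4, below them (5.83 to 5.84). SNCAIP was at 10.9 on Dox1000 replicate 1, above the others (10.7 to 10.8). All values are log2 levels.

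In each comparison only 1 of 35 splits of the 8 arrays, the real one, gave as many genes at least 2-fold different. The real and the highest other counts were 682 and 8 for Dox100 versus Ramos, 715 and 1 for Dox250, 683 and 0 for Dox500, 857 and 1 for Dox750, and 900 and 1 for Dox1000. For the successive steps they were 101 and 0, 71 and 2, 35 and 0, and 77 and 0. These splits speak of the cultures measured, which were split from 1 culture per line. Every other split mixes arrays of both lines, so low counts were to be foreseen there for any pair of distinct cultures. The splits therefore cannot exclude that single cultures came to differ by chance.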

How the results depend on the processing

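Tests chosen only after the results were seen were those of the lists without genes of chromosomes 12 and 20, of the genes around ABCB1 without ABCB1 and ABCB4, and the counts without calls that rest on a low bound, and all other alternatives were fixed before the data were examined. Signal over background limited what could be tested, with 33.3% of probes kept. Counts of genes at least 2-fold higher and lower, in the order Dox100, Dox250, Dox500, Dox750 and Dox1000 versus Ramos and then the 4 successive steps, were as follows. Without background correction they were 139 and 63, 139 and 79, 107 and 74, 152 and 126, 209 and 85, 13 and 9, 6 and 3, 4 and 0, and 16 and 0. In the deposited log2 values they were 153 and 66, 147 and 90, 118 and 79, 161 and 139, 219 and 92, 13 and 12, 6 and 3, 4 and 0, and 16 and 0. Among probes detected on all 24 arrays, where fewer genes were tested, they were 210 and 126, 219 and 151, 190 and 153, 236 and 226, 283 and 183, 11 and 19, 11 and 8, 6 and 0, and 36 and 4. Without the fold floor, which admits every gene that passed, they were 2300 and 2118, 2277 and 2430, 2401 and 2215, 2556 and 2466, 2632 and 2828, 497 and 786, 749 and 649, 379 and 383, and 1150 and 1111. Leaving out calls on a probe undetected in a line with a bound under 2-fold or none, they were 343 and 220, 341 and 251, 306 and 259, 376 and 345, 457 and 291, 33 and 42, 31 and 25, 27 and 2, and 57 and 7. Median scaling gave 4 lower genes from Dox750 to Dox1000. The calls held from Dox100 through Dox1000 numbered 63 higher and 25 lower without background correction, 71 and 28 in the deposited values, and 98 and 48 among probes detected on all 24 arrays. For the counts without background correction, in the deposited values and under median scaling the cause was not tested. Of the alternative counts, 142 lay within 1.5 times the main one, 17 of them those without low bounds, and 74 did not. All 144 counts with 1 array left out lay within 1.5 times the main one. Those ran, higher then lower in the same order, from 420 to 447 and 247 to 281, 400 to 424 and 298 to 328, 365 to 397 and 289 to 325, 444 to 489 and 395 to 417, 568 to 607 and 314 to 349, 37 to 44 and 59 to 78, 35 to 49 and 33 to 40, 26 to 34 and 4 to 5, 63 to 79 and 6 to 12. With an estimated correlation between genes, 35 list calls were lost, and the cause was not tested. Of these, 18 were in Dox100 (4), Dox250 (3), Dox500 (3) and Dox750 (8) against Ramos, with the values given beside each list, and 17 in Dox1000 and the steps. In Dox1000 versus Ramos they were double-strand break repair (0.0846), plasma cell genes (0.103), DNA replication (0.163), the ATF4 response (0.0957) and heat shock proteins (0.163). From Dox100 to Dox250 it was the ATF4 response (0.481). From Dox250 to Dox500 they were genes around ABCB1 (0.0592), B cell identity (0.19), interferon-stimulated genes (0.19), the ATF4 response (0.337) and glycolysis (0.385). From Dox500 to Dox750 they were glutathione and NRF2 targets (0.0546), the ATF4 response (0.447) and lysosome genes (0.2). From Dox750 to Dox1000 they were anti-apoptotic genes (0.0789), NF-kB targets (0.102) and heat shock proteins (0.0789). Among the lists of Dox1000 versus Ramos, genes around ABCB1 passed without background correction (0.0312), in the deposited values (0.0311), with no filter on dim probes (0.0372) and without genes of chromosomes 12 and 20 (0.0316). Anti-apoptotic genes passed with no filter (0.0265). Plasma cell genes did not pass under median scaling (0.0503), with the mean over probes of a gene (0.0569) or without genes of chromosomes 12 and 20 (0.158), nor did double-strand break repair among probes detected on all 24 arrays (0.0561) or without those chromosomes (0.0952). Their causes were not tested. With 1 array left out, adjusted p ran from 0.0458 to 0.0918 for genes around ABCB1, from 0.031 to 0.0503 for plasma cell genes and from 0.0345 to 0.0889 for double-strand break repair. List tests of the 4 successive steps and of the 4 earlier lines against Ramos were run with both correlations but under no other alternative, except that the genes around ABCB1 were tested without ABCB1 and ABCB4 at each step, which changed no call with the preset correlation. Of the named genes, 11 values in other settings and 5 with 1 array left out newly passed, 1 and 7 no longer passed, and 0 reversed. With the replicate block, in which arrays with the same number share a term, all 18 counts, the 27 lists of Dox1000 versus Ramos and all named genes kept their side, with 576 higher and 324 lower genes in Dox1000. The numbers did not pair the arrays, since the 60 same-number pairs had a mean residual correlation of -0.00997 (range -0.223 to 0.151) and 5 of 24 arrays lay closest to their own number. A slide block was not run, since slides are not given in the sources used here.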

Other observations

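Tests chosen only after the result was seen were those of a few strongly changed genes, of whole-chromosome copies, of a chromosome break and of the end of chromosome 7, and the others were fixed before their results were seen. Some genes changed in opposite directions at different steps, of which 3 are given here, singled out after their values were seen. Successive steps share the arrays of the line between them, so a low value in that line alone gives a fall and then a rise. TNFRSF17, the B cell maturation antigen, fell by 0.90 ± 0.09 from Dox250 to Dox500, rose by 0.88 ± 0.09 from Dox500 to Dox750 and fell by 0.39 ± 0.09 from Dox750 to Dox1000 (limma adjusted p = 2.91e-07, 9.49e-07 and 0.00294, n = 4). CST3, the protease inhibitor cystatin C, fell by 1.53 ± 0.16 and then rose by 0.69 ± 0.16 and by 0.61 ± 0.16 at the same steps (limma adjusted p = 5.72e-07, 0.0101 and 0.00807). CHEK2, a DNA damage kinase, fell by 0.81 ± 0.09 from Dox250 to Dox500 and rose by 0.41 ± 0.09 from Dox750 to Dox1000 (limma adjusted p = 2.74e-06 and 0.00288). In a principal component analysis Ramos lay apart from all resistant lines on the first component, which held 48.9% of the variance (mean -50.7 ± 1.39 SD, and 1.60 in Dox100 to 17.7 in Dox1000). The second (12.4%) ran from -20.4 in Dox100 to 18.3 in Dox1000.

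Genes of chromosomes 12 and 20 were higher than other genes in all 5 resistant lines against Ramos, with medians of 0.42 to 0.45 over 532 genes and 0.41 to 0.50 over 284. The shift was spread over most of these genes, with at least 82.7% positive in every line, against at most 55.2% on any other chromosome. A large positive share follows from medians this far above 0, so it is no separate test of a few strongly changed genes. Chromosomes 12 and 20 were also singled out on these same fold changes, so a higher share than elsewhere was to be foreseen. Background or scaling is argued against by the lowest median of 0.274 under 3 other processings, against at most 0.095 on any other chromosome, and probe brightness by the lowest median of 0.251 over 3 classes of genes by mean level, against at most 0.142. Of the 3 processings, no background correction and the deposited values are nearly the same, with chromosome 12 medians of 0.277 and 0.288 in Dox100. As a hypothesis, the lines may differ from Ramos in copies of the whole chromosomes, since 100% of windows of 25 neighbouring genes lay above the median of all genes in every line. That bar is low. The last full window of chromosome 20, from ADRM1 to TPD52L2, had medians of 0.19, 0.176, 0.356, 0.159 and 0.044 in the 5 lines in order of dose. The last of chromosome 12, from TMED2 to FBRSL1, had 0.197 in Dox750 and 0.167 in Dox1000. A difference in only part of each chromosome thus stays open. All 5 comparisons share the Ramos arrays, so fewer copies in Ramos fit as well as more in the resistant lines, and DNA was not analysed here.

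Genes beyond ABCB1 on chromosome 7 were lower in Dox250 than in Dox100, the step at which ABCB1 rose most but not the only one, with a median of -0.43 over 245 genes. Of these, 79.6% were negative, so the shift was spread over most of them. Whole other chromosomes reached at most 63.9%, an unlike comparison, since no segments of other chromosomes were searched. As wholes, chromosome 7 had 35.5% of genes positive and chromosome 19 had 36.1%. The median beyond ABCB1 stayed at -0.233 or lower under 3 other processings. It stayed at -0.34 or lower in each of 3 classes of genes by mean level. This persistence argues against background, scaling and brightness. Whole other chromosomes had -0.056 or higher and -0.132 or higher, again an unlike comparison. Of the 3 processings, no background correction (-0.233) and the deposited values (-0.237) are nearly the same. As a hypothesis, the lower genes may reflect a chromosome break close to ABCB1, which no test here decides: a block of 165 lower genes, from GTPBP10 to CNOT4 (median -0.49, permutation p = 0.001, the smallest that 1000 permutations can give), started 5 genes beyond ABCB1, as near as 2.34% of possible starts, but this restates a pattern already split at ABCB1. Loss of everything beyond the break at this step is argued against by the 71 genes from TRIM24 to VIPR2 at the end of the chromosome, which had a median of -0.002 here. These genes were found by a scan for lower genes from Dox250 to Dox500, so their median of -0.39 there is the value they were picked on. A loss within the arm, a mixture of cells and a loss unrelated to ABCB1 stay open, and DNA was not analysed here.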
